A study of Mus musculus with 4 samples.

How the data were processed

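RNA was measured in peritoneal macrophages of C57BL/6 mice kept on a control diet or on a high-fat diet that supplied 60% of its energy as fat. The feeding lasted 12 weeks, and 4 days before collection the mice had received 3% thioglycollate medium into the peritoneal cavity, an irritant that draws macrophages into it. Total RNA was depleted of ribosomal RNA and sequenced as paired-end libraries, per the labels' protocols, so transcripts without a poly(A) tail could be counted too. Each diet had 2 libraries, and the labels do not say whether these came from separate mice or from pools. The p-values of single genes therefore measure the spread between these samples only, which may be technical.

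The deposited values are raw read counts per gene, whole numbers with no normalization, in 1 table per library. TopHat2 2.0.10, Cufflinks 2.1.1 and HTSeq are named with the mm9 genome build, per the submitters' processing notes. Their order and settings, including whether reads were counted by strand, are not given in the sources used here. The authors also deposited the gene models on which the counts rest, and their exon positions are coordinates on mm9, with the first base of a chromosome numbered 1. These models hold 24625 genes, of which 20679 have a RefSeq protein-coding transcript, 3471 have RefSeq noncoding transcripts only, and 475 carry assembly names outside RefSeq, called assembled genes here. Of the assembled genes, 472 have 2 or more exon blocks; how they were selected is not given in the sources used here. Current symbols were looked up by transcript accession in a GRCm38 gene table, which matched 23868 of 24150 RefSeq genes, and no coordinate was taken from that build.

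The 5 summary lines of each count table name no gene and were left out of library sizes and tests. Alignments at more than 1 place made up 37.5% to 48.5% of all counted lines, reads in no gene model 13.5% to 15.0%, and reads matching more than 1 gene 0.664% to 0.823%. Gene totals ran from 39347347 to 45658551 counts per library, and 15641 to 15967 genes had at least 1 count. Replicates were compared by a chi-square test of their counts over genes: the statistic per degree of freedom was 33.8 between the control libraries and 34.9 between the high-fat libraries, far above sampling noise in both, so none looks like a copy of another, and each was counted as 1 library. This does not show that the libraries came from separate animals.

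Genes were kept by filterByExpr of edgeR 4.0.16 with its default minimum count of 10 and minimum total of 15, which left 12747 genes (12303 RefSeq, 444 assembled). The main comparison was edgeR's quasi-likelihood test with robust fitting, TMM normalization and diet as the only term, leaving 2 residual degrees of freedom. P-values were adjusted over all kept genes by Benjamini-Hochberg, with a threshold of 0.05. Fold changes are high-fat over control on the log2 scale, and each standard error is the size of the log2 fold change divided by the square root of the test's F value. Levels are CPM, each gene's count scaled to its library's TMM-adjusted total, given as mean ± SD of 2 libraries.

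Before the data were examined, 35 gene lists were fixed from textbook knowledge, 22 of pathways or gene classes and 13 of cell type markers. The 33 lists with at least 5 kept genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera rests on the 2 residual degrees of freedom, so passing after adjustment over 33 lists was nearly out of reach. Camera asks whether a list moved relative to other genes, while fry asks whether its genes moved, on balance, in the same direction. With the preset correlation the camera p rests on the spread across genes, which are not independent replicates. It does not measure the spread between samples. The named genes also follow a rule fixed at that time. Of RefSeq genes past the threshold, with both high-fat libraries on the same side of both control libraries and a mean of at least 5 CPM, the 10 with the highest and the 10 with the lowest log2 fold change were picked. Up to 4 members with the smallest p are named for each list that passed or holds a gene past the threshold, whether these genes passed or not, as are 3 assembled genes per direction at a mean of at least 1 CPM, filled by smallest p where fewer passed, and 5 macrophage identity genes. Some genes that the rule picks are not reported here by name or drawn; counts and list results include them. Genes named outside this rule are marked as chosen after their values were seen.

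The log2 fold change of each kept assembled gene was correlated with that of the nearest kept RefSeq gene on its chromosome, with 100000 permutations of the pairing, two-sided. Of the RefSeq genes kept, 8 are entries with no gene name, most of which join transcripts from several places on a chromosome; they stayed in the tests and were not taken as neighbours, a choice made after seeing the data. These correlations run across genes, which are not independent replicates. Alternatives fixed beforehand covered other size factors, other filters, a replicate block, each library left out, RefSeq genes only, other thresholds, DESeq2 1.42.0, limma-voom, and edgeR's exact and non-robust tests. Added after seeing the data were the neighbour correlation with these entries as neighbours, a fit without genes whose exons overlap another gene, and a fit with each library's trend on GC content and exon length removed. GC content was taken by gene symbol, from the longest GENCODE transcript on GRCm38, for 99.4% of kept RefSeq genes and could not be had for assembled genes, whose mm9 sequence was not used here. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.

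The test was tried on simulated counts for 12747 genes with the real means, library sizes and dispersions, in 10 runs with 200 changed genes each. For the diet comparison it recovered 35.5% of genes changed 1.5-fold, 71.2% of those changed 2-fold and 93.2% of those changed 4-fold. Of its calls 14.3% were false when each gene kept its own estimated dispersion (9.29% to 22.5% over the runs), above the nominal 5%. With dispersions taken from the trend of all genes, 4.33% were false (2.29% to 7.53%). The adjusted p-values of single genes may thus understate the false calls where dispersions differ much between genes. For the gene lists, camera called 0 of 330 unchanged simulated lists and a list lowered 1.5-fold in 10 of 10 runs; these simulated genes varied independently, so shared variation of a list's genes between samples was not covered. For the neighbour correlation, 3% of 100 simulated null runs over 444 pairs passed 0.05, and a true correlation of 0.3 was recovered as 0.275 on average.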

Results

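Gene expression was compared between macrophages from the peritoneal cavity of mice fed a control diet and of mice fed a high-fat diet, to find transcripts that differ with diet. Each diet had 2 libraries. Counts on genes were 39846646 and 39347347 in control replicates 1 and 2, and 45658551 and 40527591 in high-fat replicates 1 and 2. Macrophage transcripts were abundant in both diets: Lyz2, encoding lysozyme, stood at 22512 ± 591 CPM with control diet and 18697 ± 3250 CPM with high-fat diet (SD, n = 2 per diet, as for all levels given). Replicates correlated at r = 0.993 (control) and 0.990 (high-fat) across genes on the log2 CPM scale, and libraries of different diets at 0.984 to 0.987. The leading principal component held 54.3% of the variance and separated the diets; this structure was described without a test.

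Among called RefSeq genes with a mean of at least 5 CPM, the 10 with the highest log2 fold changes included genes of a metalloreductase, a complement protease and an inhibitor of lipoprotein lipase. Steap4, the metalloreductase gene, rose from 1.18 ± 0.0123 to 8.99 ± 2.21 CPM, a log2 fold change of 2.93 ± 0.24 (SE; adjusted p = 0.00563, edgeR quasi-likelihood test). C1s1, a serine protease of the classical complement pathway, rose from 1.99 ± 0.319 to 11.7 ± 4.37 CPM (log2 fold change 2.56 ± 0.29, adjusted p = 0.0166). Angptl4, an inhibitor of lipoprotein lipase, rose from 8.02 ± 0.0982 to 23.8 ± 7.73 CPM (1.57 ± 0.22, adjusted p = 0.0350), and Agpat9 (now Gpat3), a glycerol-3-phosphate acyltransferase, from 3.17 ± 0.330 to 7.70 ± 1.08 CPM. The secreted carbonic anhydrase Car6 (log2 fold change 1.66), the serotonin synthesis enzyme Tph1 (1.52), the adhesion molecule Vcam1 (1.15) and the neutrophil chemoattractant Cxcl1 (1.01) rose as well. The asparagine synthetase gene Asns had the smallest standard error of the 10 higher genes picked by the fixed rule and rose from 65.8 ± 4.09 to 130 ± 2.34 CPM (log2 fold change 0.99 ± 0.10). Plod2, a lysyl hydroxylase that modifies collagen, rose from 3.71 ± 0.298 to 7.43 ± 0.0975 CPM; its exons overlap an antisense gene, and whether counting used strand is not given in the sources used here. Markers of mesothelial cells and fibroblasts were higher in the same libraries, with a median log2 fold change of 1.92 over 17 genes.

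Among called RefSeq genes with a mean of at least 5 CPM, the 10 with the lowest log2 fold changes included genes of a protease, a cell cycle inhibitor and a noncoding RNA. Mmp9, a gelatinase abundant in neutrophils, went from 19.8 ± 2.28 to 7.13 ± 1.59 CPM, a log2 fold change of -1.48 ± 0.18 (adjusted p = 0.0161, edgeR quasi-likelihood test), and Cdkn1c, a cyclin-dependent kinase inhibitor, from 39.1 ± 2.06 to 16.6 ± 3.35 CPM (-1.23 ± 0.15). Coagulation factor F5 (log2 fold change -1.53), Tmem178 (-1.53), Tceal7 (-1.18), Fstl1, a secreted glycoprotein (-1.12), and the integrin subunit Itgb3 (-0.96) fell too. F5 overlaps an antisense gene and carries the same doubt as Plod2. Rmrp, the RNA component of the RNase MRP complex and encoded at chromosome 4: 43505657 to 43505931 (mm9, minus strand, 1 exon), fell from 1096 ± 38.1 to 553 ± 68.7 CPM (-0.99 ± 0.12, adjusted p = 0.0163). Rpl36 fell by 1.03 on the log2 scale; ribosomal protein genes have many near-identical pseudogenes, so this value is uncertain.

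**Figure D1:**
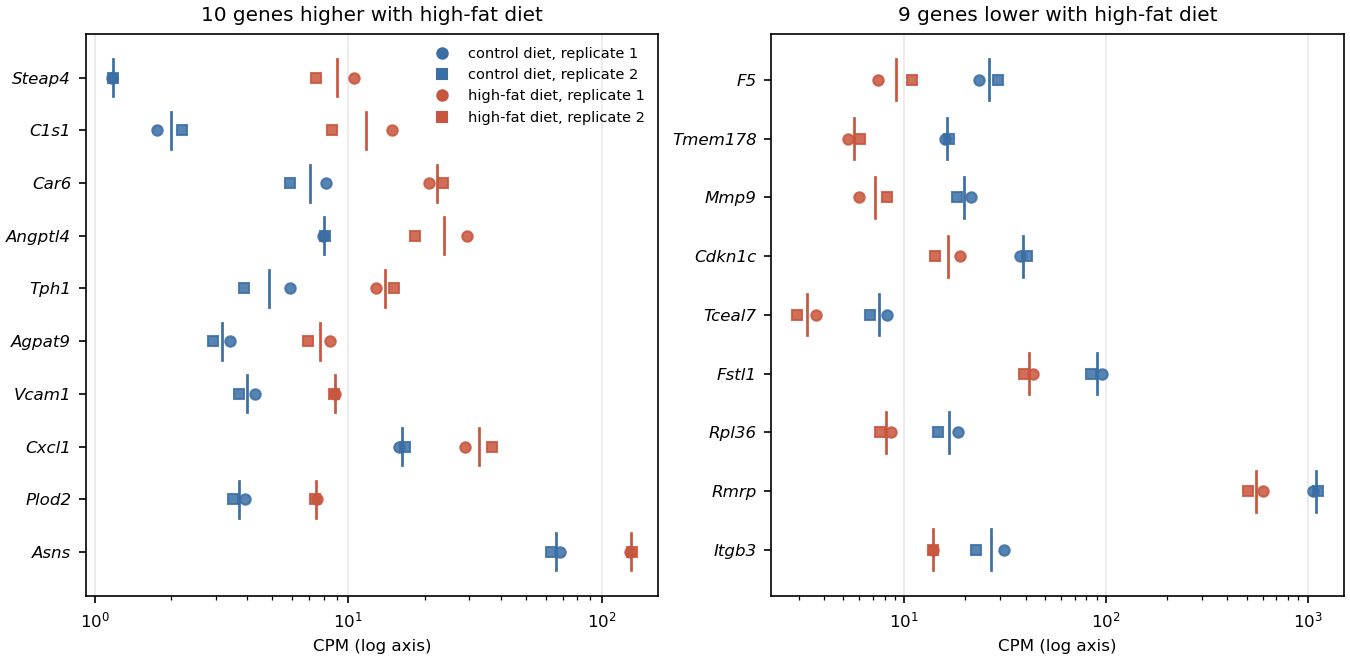
CPM (log axis) of 10 genes with the highest and 9 of those with the lowest log2 fold change by the fixed rule, with circles for replicate 1, squares for replicate 2 and lines at the diet means of 2 libraries. In each gene both high-fat libraries lie on the same side of both control libraries; Steap4 runs from 1.18 to 8.99 CPM and Rmrp from 1096 to 553 CPM at the means.

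In the edgeR quasi-likelihood test 78 of 12747 genes passed an adjusted p of 0.05, 41 higher and 37 lower with high-fat diet, and in all 78 the diets' libraries did not overlap. Among all kept genes 51.0% were so separated, against 33.3% by chance for a single gene with 2 libraries in each diet. Genes that share variation between libraries move together, so the excess does not tell diet from another difference between the libraries. Of the called genes, 26 RefSeq genes lay under 5 CPM, 22 of them higher. The count moved from 78 to 16 without control replicate 1, 3 without control replicate 2, 823 without high-fat replicate 1 and 452 without high-fat replicate 2. It was 70 with RefSeq genes only and 9 with the GC content and exon length trend removed, a check chosen after seeing the data that covered 12225 RefSeq genes and no assembled genes. Without control replicate 1, 6 of the 20 genes picked by the fixed rule stayed past the threshold, and without control replicate 2, 1 of the 20. With the GC content and exon length trend removed 4 of the 20 passed, and by limma-voom 11; their direction held in every fit run.

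Genes of sterol biosynthesis fell as a list. Of 23 measured members 22 had a log2 fold change below 0, with a median of -0.60, and 21 had both high-fat libraries below both control libraries. Lss (-0.91 ± 0.15), Fdps (-0.79 ± 0.13) and Mvd (-1.30 ± 0.22), enzymes of the path from mevalonate to cholesterol, were among the 4 members that fell over all genes, with the doubt of an antisense overlap for Lss, and 18 members passed when adjusted over the list alone. The camera adjusted p was 3.9e-10 with the preset correlation, and adjusted p = 0.537 with an estimated correlation. The list's call held without each of the 4 libraries in turn, with medians from -0.77 to -0.46, but the 4 members called over all genes became 0 without control replicate 1, 0 without control replicate 2, 6 without high-fat replicate 1 and 16 without high-fat replicate 2. DESeq2 called 13 members, against 2 with a replicate block, 0 with a CPM filter, 0 by limma-voom and 0 with the GC content and exon length trend removed.

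Other lipid genes went both ways. In the fatty acid synthesis list 14 of 21 members lay below 0, with a median of -0.23 (camera adjusted p = 0.0289; adjusted p = 0.739 with an estimated correlation). None of its members passed over all genes by edgeR, against 9 at an unadjusted p under 0.05 and 3 lower by DESeq2, and 5 lower when adjusted over the list alone. Fasn, the fatty acid synthase, had a log2 fold change of -1.56 ± 0.30, and Acaca, Lpin1 and Elovl6 had -0.46, -0.58 and -0.64. The list's call ended without control replicate 1 (adjusted p = 0.169), control replicate 2 (0.0575) or high-fat replicate 1 (0.138), and with a replicate block (0.0511). Over all genes 1 member was called higher and 4 lower without high-fat replicate 1, and 5 lower without high-fat replicate 2. In the list of lipid uptake, storage and PPAR targets, 2 of 30 members rose over all genes, Angptl4 and Vldlr, a lipoprotein receptor with 2 and 1 counts in the control libraries and 34 and 22 in the high-fat libraries. These calls became 0 without either control library, and 5 higher and 2 lower without either high-fat library. Adjusted over the list alone, 6 were higher and 3 lower, and the list as a whole did not pass (camera adjusted p = 0.135). Slc25a20, a mitochondrial carnitine carrier, and Hilpda, a lipid droplet protein, had log2 fold changes of 0.54 and 0.53 and missed the threshold over all genes. The list of LXR targets and cholesterol efflux did not pass (median -0.039, camera adjusted p = 0.282), and its 19 members gave 0 calls over all genes by edgeR, 7 at an unadjusted p under 0.05, and 1 higher and 2 lower by DESeq2. Adjusted over the list alone 1 member was higher and 3 lower, among them the cholesterol exporter Abca1 (-0.57) and Srebf1 (-0.81), with the phospholipid transfer protein Pltp at 0.63; these 3 were chosen after their values were seen, and the exons of Srebf1 and Pltp overlap antisense genes.

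Markers of mesothelial cells and fibroblasts rose as a list. All 17 measured members had log2 fold changes above 0, with a median of 1.92, and 15 had both high-fat libraries above both control libraries. Lum, a matrix proteoglycan, rose from 0.215 ± 0.0234 to 1.48 ± 0.433 CPM over all genes, and 13 members passed when adjusted over the list alone. With 8 and 9 counts in the control and 83 and 47 in the high-fat libraries, Lum passed the filter through the high-fat libraries alone. Such members could only come out higher, so the shared direction is partly set by the filter. With control diet 6 of the 17 members reached 1 CPM. Pdgfra, a receptor for platelet-derived growth factor, stood at 1.94 ± 0.103 and 13.5 ± 6.98 CPM, with Col1a1 at 0.227 and 0.927 and the uroplakin gene Upk1b at 0.353 and 1.15 CPM. The camera adjusted p was 5.6e-11, and adjusted p = 0.537 with an estimated correlation. The call held without each library in turn, with medians from 1.34 without high-fat replicate 1 to 2.23 without high-fat replicate 2. The count of members called over all genes went from 1 to 0 without either control library, 7 without high-fat replicate 1 and 13 without high-fat replicate 2; DESeq2 called 6, and 0 were called with the GC content and exon length trend removed.

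**Figure D2:**
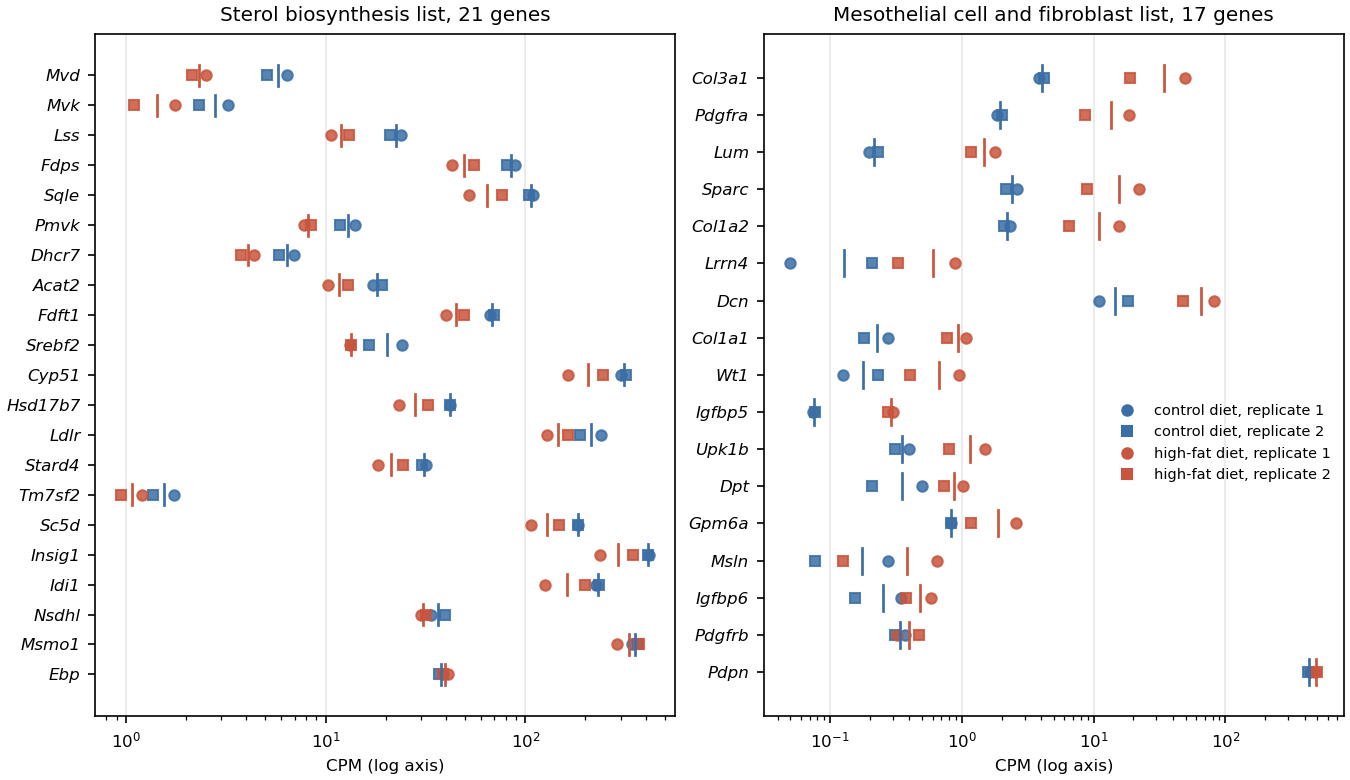
CPM (log axis) in each library of 21 sterol biosynthesis genes and the 17 measured markers of mesothelial cells and fibroblasts, with circles for replicate 1, squares for replicate 2 and lines at the means of 2 libraries. In 19 of the 21 sterol genes drawn both high-fat libraries lie below both control libraries, and in 15 of the 17 markers they lie above.

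Markers of other leukocytes moved in both directions. Neutrophil markers fell as a list, with 12 of 15 members below 0 and a median of -0.76 (camera adjusted p = 0.00214; adjusted p = 0.537 with an estimated correlation). Mmp9 and Csf3r, the receptor for granulocyte colony-stimulating factor (-0.69 ± 0.12), fell over all genes, and 4 members fell when adjusted over the list alone, with Padi4 at -1.51 and Retnlg at -4.06. The list's call held without each library in turn, while the members called over all genes numbered 1 without control replicate 1, 0 without control replicate 2, 6 without high-fat replicate 1 and 5 without high-fat replicate 2. B cell markers rose as a list, with 19 of 20 members above 0 and a median of 0.73 (camera adjusted p = 0.0123; adjusted p = 0.739 with an estimated correlation). Igj, the immunoglobulin joining chain, rose from 0.903 ± 0.435 to 3.36 ± 0.430 CPM and was the only member to pass over all genes or when adjusted over the list alone. Without high-fat replicate 1, 18 of the 20 members were called higher, and 0 were called without either control library, with a CPM filter, with RefSeq genes only, without overlapping genes, without robust fitting, with a replicate block, by limma-voom or with the GC content and exon length trend removed. Among its other members with small p, Mzb1 and Cr2 had log2 fold changes of 1.09 and 1.20, and Cd22 had -0.34. This list rested on high-fat replicate 2: without it the median was -0.11 (adjusted p = 0.471), against 1.28 without high-fat replicate 1. Without control replicate 2 the adjusted p was 0.0577, and with the GC content and exon length trend removed it was 0.0553. The dendritic cell list did not pass (median -0.018, camera adjusted p = 0.0649). Its lectin gene Cd209a fell from 3.91 ± 0.508 to 0.775 ± 0.213 CPM, and 6 members were lower when adjusted over the list alone, including Flt3 (-1.69), Siglech (-2.08) and Clec9a (-2.06). Over all genes its calls became 0 without either control library, 3 higher and 5 lower without high-fat replicate 1, and 3 lower without high-fat replicate 2.

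Apart from general macrophage markers, the remaining cell type lists did not pass or were too small to test. In the eosinophil list (median -0.47 over 7 genes, camera adjusted p = 0.102) the lipoxygenase gene Alox15 fell from 2.20 ± 0.199 to 0.428 ± 0.209 CPM, and 3 members were lower when adjusted over the list alone, with Siglecf at -1.32 and Ccr3 at -2.22. Its 1 call over all genes became 0 without control replicate 2, 1 higher and 3 lower without high-fat replicate 1, and 3 lower without high-fat replicate 2. Markers of large peritoneal macrophages had a median of -0.075 (camera adjusted p = 0.413), with Alox15 as the member called over all genes and also when adjusted over the list alone; the calls became 1 higher without control replicate 1, 0 without control replicate 2, 2 higher and 1 lower without high-fat replicate 1, and 1 higher and 3 lower without high-fat replicate 2. Markers of monocytes and small peritoneal macrophages had a median of 0.023, a mean of -0.033 and a camera direction of lower (adjusted p = 0.429). Fn1, encoding fibronectin, fell there from 397 ± 58.1 to 226 ± 6.42 CPM, and 4 members were lower when adjusted over the list alone, among them F10 (-0.55) and Hp (-1.11). Calls over all genes in that list became 0 without either control library, 5 higher and 3 lower without high-fat replicate 1, and 5 lower without high-fat replicate 2. T cell and NK cell markers had a median of 0.48, higher by camera (adjusted p = 0.813) but lower by fry (adjusted p = 0.961). Mast cell and basophil markers had a median of 0.11 (camera adjusted p = 0.355), and endothelial markers -0.16 over 6 genes (0.413), with 2 members lower when adjusted over the list alone. In these last 3 lists edgeR called 0 members over all genes, with 2, 1 and 2 at an unadjusted p under 0.05, and DESeq2 called 1, 0 and 0. The adipocyte list and the list of erythroid cells and platelets kept 3 genes each and were not tested; Lpl, also made by macrophages, was the only one of these 6 genes to pass when adjusted over the list alone, at -0.44. Over all genes edgeR called 0 of them, against 1 at an unadjusted p under 0.05 and 1 by DESeq2.

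General macrophage markers fell slightly as a list, with 14 of 15 members below 0 and a median of -0.15 (camera adjusted p = 0.0158; adjusted p = 0.537 with an estimated correlation). Mertk, a receptor for dying cells, fell from 59.4 ± 1.04 to 36.8 ± 5.47 CPM over all genes, and 3 members fell when adjusted over the list alone, with Csf1r at -0.52 and Maf at -0.53. Of the identity genes, Emr1 (now Adgre1, encoding F4/80) had a log2 fold change of -0.077, Cd68 0.14, Itgam -0.18 and Lyz2 -0.27; with Csf1r, none of these 5 passed over all genes. The list's call ended without control replicate 2 (adjusted p = 0.0575) or high-fat replicate 1 (0.0740), and the members called over all genes became 0 without either control library and 3 without high-fat replicate 1. By fry this list and MHC class I presentation passed (adjusted p = 0.0361 for both), and no other list did.

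Antigen presentation and phagocytosis lists fell. MHC class I presentation had 13 of 14 members below 0 and a median of -0.20 (camera adjusted p = 0.00574; adjusted p = 0.537 with an estimated correlation), with the immunoproteasome subunits Psmb8, Psmb9 and Psmb10 at -0.45, -0.47 and -0.47 and H2-T23 at -0.55. Its call held without each library in turn, and 3 members were called lower over all genes without high-fat replicate 1. MHC class II presentation had 10 of 13 below 0 and a median of -0.21 (0.0289; adjusted p = 0.739 with an estimated correlation), with H2-DMa at -0.67, Cd74 at -0.51, H2-Eb1 at -0.51 and Ciita at -0.75. Over all genes edgeR called 0 members of either list, against 5 and 4 at an unadjusted p under 0.05 and 2 in each by DESeq2; adjusted over the list alone 1 and 4 were lower. The class II call ended without control replicate 2 (adjusted p = 0.161), high-fat replicate 1 (0.908) or genes that overlap others (0.0699). Its median was -0.073 without high-fat replicate 1, with 2 members called higher over all genes, and -0.44 without high-fat replicate 2, with 3 called lower. The list of complement, Fc receptors and phagocytosis had a median of -0.19 (0.0469; adjusted p = 0.560 with an estimated correlation), with Mertk called over all genes and 2 higher and 6 lower when adjusted over the list alone. Havcr2, an inhibitory receptor, and the scavenger receptor Cd36 had log2 fold changes of 0.78 and 0.55, and the integrin Itgax had -0.37. Its call ended without control replicate 1 (median -0.10, adjusted p = 0.116), high-fat replicate 1 (0.256) or overlapping genes (0.0655), and with upper-quartile factors (0.0505) or a replicate block (0.0800). Over all genes 0 of its members were called without control replicate 1, 2 higher and 3 lower without high-fat replicate 1, and 2 higher and 5 lower without high-fat replicate 2. The list of lysosomal and lipid-associated macrophage genes had a median of -0.17 (0.0123; adjusted p = 0.560 with an estimated correlation), with Tyrobp at -0.45, Itgax at -0.37, Lpl at -0.44 and Fabp5 at -0.41. None of its 34 members passed over all genes or when adjusted over the list alone by edgeR, with 8 at an unadjusted p under 0.05 and 4 lower by DESeq2. The call ended without control replicate 2 (adjusted p = 0.0555) or high-fat replicate 2 (median -0.11, adjusted p = 0.103), and 2 members were called lower over all genes without high-fat replicate 1.

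Inflammatory, interferon and stress lists went in different directions. The list of inflammatory cytokines, chemokines and mediators did not pass (median 0.15, camera adjusted p = 0.0860). Cxcl1 rose over all genes, and 7 members were higher and 1 lower when adjusted over the list alone, with Il6 at 0.127 ± 0.00320 and 0.689 ± 0.335 CPM, Cxcl3 at 2.24 and 6.56 CPM, and Nfkbia, an NF-kB inhibitor, at 0.41 on the log2 scale. Members called over all genes went from 1 to 0 without either control library, 13 higher and 1 lower without high-fat replicate 1, and 2 higher and 2 lower without high-fat replicate 2. Interferon-stimulated genes fell as a list, with 31 of 38 members below 0 and a median of -0.15 (0.0360; adjusted p = 0.801 with an estimated correlation). Slfn5, whose exons overlap an antisense gene, had a value of -0.38, and Mx1, Oas1a and Zbp1 had -0.50, -0.33 and -0.45. In all, 0 members passed by edgeR over all genes, when adjusted over the list alone, or by DESeq2, with 4 at an unadjusted p under 0.05. That call ended without overlapping genes (adjusted p = 0.0592), without control replicate 2 (median -0.095, adjusted p = 0.194) or without high-fat replicate 2, where the median was 0.012 (0.808), against -0.31 without high-fat replicate 1, where 4 members were called lower. The list of immediate-early and heat-shock genes rose, with 23 of 34 members above 0 and a median of 0.17 (0.0303; adjusted p = 0.801 with an estimated correlation). Fos, a transcription factor subunit, rose from 59.9 ± 2.16 to 89.5 ± 2.39 CPM, and 2 members rose when adjusted over the list alone, the other being the co-chaperone Dnaja1 at 0.43, with Dusp1 at 0.44 and Ier3 at 0.71. Its call ended without overlapping genes (adjusted p = 0.0794), with no filter (0.0633), without control replicate 2 (median 0.10, adjusted p = 0.194) or without high-fat replicate 2, where the median was -0.074 (0.829), against 0.31 without high-fat replicate 1, where 8 members were called; 0 were called without either control library. Unfolded protein response genes rose as a list, with 22 of 29 above 0 and a median of 0.092 (0.0372; adjusted p = 0.537 with an estimated correlation). Asns was the only member called over all genes and also when adjusted over the list alone, and Manf, Atf4 and Pdia4 had 0.38, 0.26 and 0.24; the adjusted p lay from 0.0724 to 0.185 when any of the 4 libraries was left out, so each ended the call, as did no filter (0.0690), and the median was 0.061 and 0.14 without control replicates 1 and 2. Over all genes 0 members were called without control replicate 2 and 2 without high-fat replicate 1. The alternative activation list did not pass, and its median (-0.11) and mean (0.017) differed in sign (camera higher, adjusted p = 0.970). Its lectin gene Clec10a rose by 0.88 ± 0.13 and Fn1 fell, with 3 members higher and 2 lower when adjusted over the list alone, Clec7a at -0.68 and Cd36 at 0.55 among them; its calls over all genes became 0 without either control library, 6 higher and 3 lower without high-fat replicate 1, and 1 higher and 5 lower without high-fat replicate 2.

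Ribosomal proteins, glycolysis and cell cycle genes made up the other lists that passed. Cytosolic ribosomal protein genes fell as a list, with 37 of 43 members below 0 and a median of -0.16 (camera adjusted p = 0.00022, and 0.577 with an estimated correlation). The doubt from near-identical pseudogenes given for Rpl36 holds for these genes too. Rps14 fell from 386 ± 2.24 to 263 ± 11.1 CPM over all genes, and 9 members fell when adjusted over the list alone, with Rpl18 and Rps9 at -0.57 and -0.46; the call ended without control replicate 2 (median -0.091, adjusted p = 0.0575), and the median was -0.26 without control replicate 1. Its 1 call over all genes became 0 without either control library, 7 without high-fat replicate 1 and 3 without high-fat replicate 2. Glycolysis genes fell as a list, with 20 of 24 below 0 and a median of -0.22 (camera adjusted p = 0.0372, and 0.739 with an estimated correlation). Among them were Eno2 at -0.60, Hk3, whose exons overlap an antisense gene, at -0.52, Pdk1 at -0.32 and Pfkfb4 at -0.46. Cell cycle genes rose as a list, with 28 of 37 above 0 and a median of 0.15 (0.0275; adjusted p = 0.537 with an estimated correlation), among them Tpx2 at 0.24, Rrm1 at 0.24, Nusap1 at 0.68 and Kif11 at 0.41. In both lists 0 members passed by edgeR over all genes or when adjusted over the list alone, with 5 and 3 at an unadjusted p under 0.05 and 1 and 0 by DESeq2; without high-fat replicate 1 edgeR called 6 and 1 members lower. The glycolysis call ended without control replicate 1 (median -0.064 with 9 members above 0, adjusted p = 0.313), high-fat replicate 2 (0.103), overlapping genes (0.0763) or the GC content and exon length trend (0.0750). The cell cycle call ended without control replicate 1 (0.0738), high-fat replicate 1 (0.0834), overlapping genes (0.0794) or that trend (0.0724), and with no filter (0.0514).

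Among lists that did not pass, noncoding RNAs and matrix genes held called members. In the list of long noncoding RNAs (median -0.065, camera adjusted p = 0.0860), Rpph1, the RNA component of RNase P (-0.86 ± 0.10), Rmrp and Kcnq1ot1, an imprinted antisense transcript (-0.55 ± 0.10), fell over all genes and were the 3 members called when adjusted over the list alone; Mir17hg had -0.33. Kcnq1ot1 overlaps exons of Kcnq1 on the other strand, so its value is uncertain. The calls numbered 1 without control replicate 1 and 0 without control replicate 2. In the extracellular matrix list (median 0.10, camera adjusted p = 0.251), Mmp9 and Fn1 fell over all genes, while 8 members were higher and 6 lower when adjusted over the list alone, with Lox, a lysyl oxidase, at -1.01 and Col1a1 at 2.02. Its calls over all genes became 0 without either control library, 10 higher and 5 lower without high-fat replicate 1, and 7 higher and 3 lower without high-fat replicate 2. Histone genes had a median of 0.11 (0.0860), hypoxia genes 0.14 (0.176), NRF2 antioxidant genes -0.041 (0.458) and nuclear-encoded oxidative phosphorylation genes -0.0086 (0.723). By edgeR these last 4 lists had 0 members called over all genes, with 2, 3, 8 and 4 at an unadjusted p under 0.05, and DESeq2 called 0, 0, 3 and 1; adjusted over the list alone only NRF2 antioxidant genes had calls, with 2 lower.

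**Figure D3:**
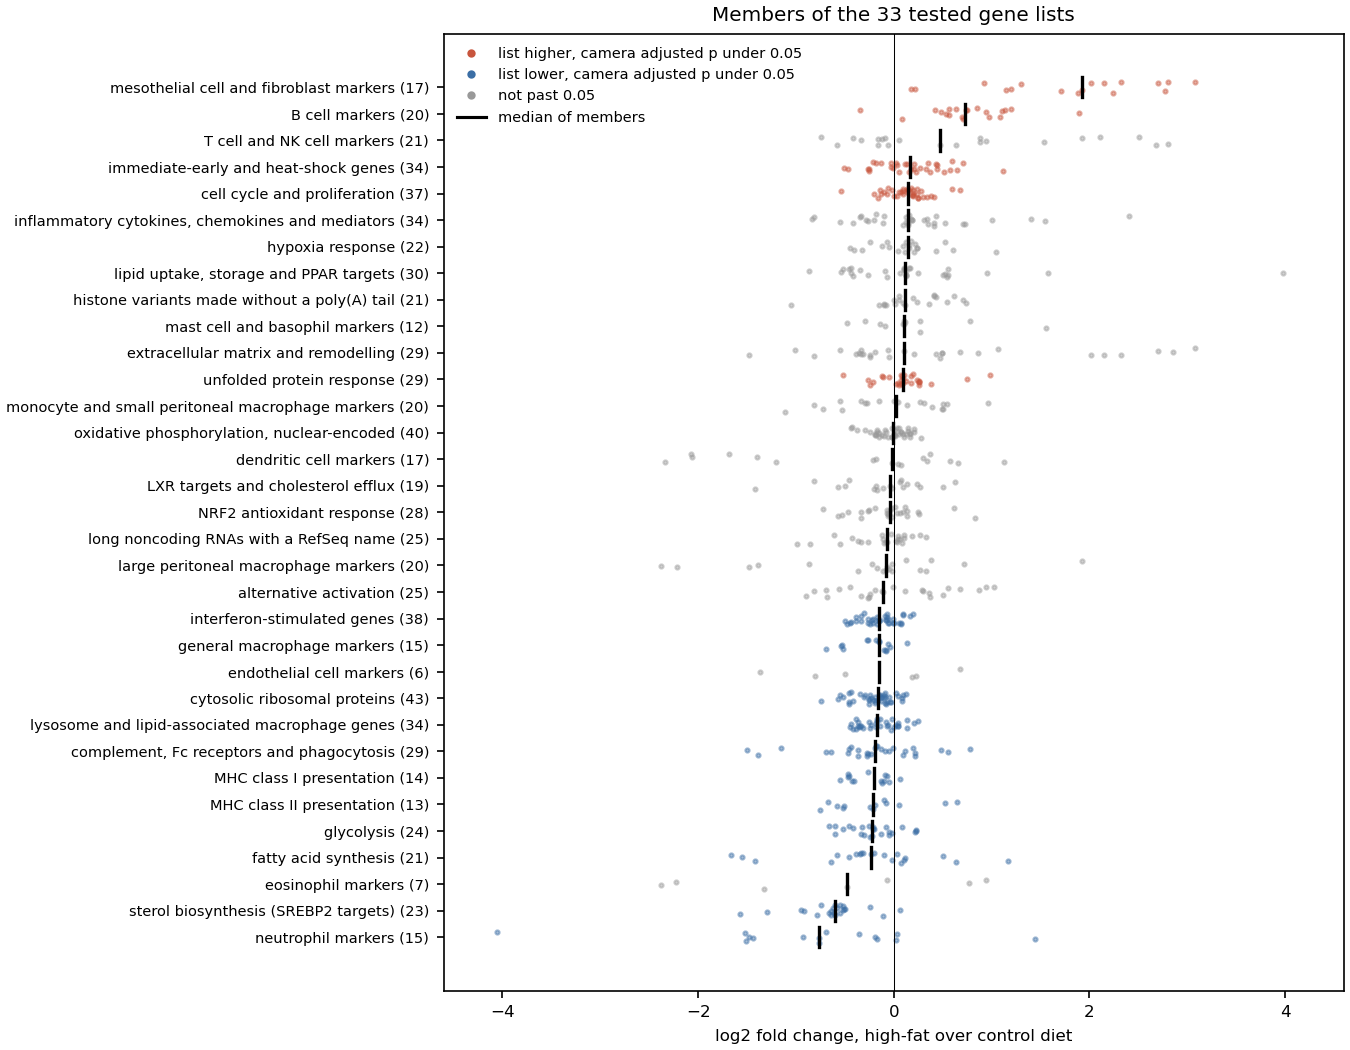
Log2 fold changes of the measured members of the 33 tested gene lists, with the number of members in brackets and a black line at each list's median. Lists past a camera adjusted p of 0.05 with the preset correlation are red (5 higher) or blue (11 lower); with an estimated correlation 0 lists passed.

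Of the 33 lists, 16 passed by camera with the preset correlation, 5 higher and 11 lower. The p-values of that form run across genes and do not measure the spread between samples. With an estimated correlation 0 lists passed by camera, the smallest adjusted p being 0.537, and 0 had an unadjusted p under 0.05, while fry called 2. That form of camera has 2 degrees of freedom, so a lost call does not by itself show shared variation. For MHC class I presentation the estimated correlation was -0.048, below the preset 0.01, yet the unadjusted camera p went from 0.00087 to 0.071. It also lay below the preset for general macrophage markers and the unfolded protein response, complement and cell cycle lists. In the other called lists it lay above the preset, from 0.025 for neutrophil markers to 0.60 for B cell markers, with 0.39 for mesothelial and fibroblast markers. Shared variation thus stays open for those lists. Of the 16 lists, 4 were called without each library in turn: sterol biosynthesis, MHC class I presentation, neutrophil markers, and mesothelial cell and fibroblast markers. Without control replicate 2, 9 lists passed. Of the 18 lists with members called over all genes, 5 held a call without control replicate 1, 1 without control replicate 2, 7 by limma-voom, 13 with a CPM filter and 2 with the GC content and exon length trend removed.

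Assembled genes, gene models outside RefSeq, lay lower with high-fat diet. Of the 444 measured, 329 (74.1%) had a log2 fold change below 0, with a median of -0.30, against 0.0071 for protein-coding and -0.18 for noncoding RefSeq genes. XLOC_008438 (chromosome 13: 52649728 to 52657129, mm9, minus strand, 5 exon blocks, 8.12 kb from Gm2848) rose from 24.4 ± 0.769 to 42.3 ± 1.02 CPM (log2 fold change 0.79 ± 0.10, adjusted p = 0.0190, edgeR quasi-likelihood test). XLOC_007427 (chromosome 13: 5885660 to 5928342, plus strand, 3 exon blocks), 16.0 kb from Klf6, rose from 16.4 ± 1.92 to 28.7 ± 3.46 CPM (0.81 ± 0.14, adjusted p = 0.0456). XLOC_029801 (chromosome 8: 130672447 to 130701979, plus strand, 3 exon blocks), with Nrp1 as its nearest measured RefSeq gene at 181 kb, fell from 58.4 ± 1.28 to 34.2 ± 2.49 CPM (-0.77 ± 0.10, adjusted p = 0.0190). XLOC_001073 (chromosome 1: 39606428 to 39607225, minus strand, 2 exon blocks), 0.74 kb from Snord89, fell from 6.45 ± 0.827 to 2.98 ± 0.0370 CPM (-1.11 ± 0.19, adjusted p = 0.0456). XLOC_020771, 6.18 kb from the lipid droplet gene Plin2, had a log2 fold change of 0.80 (adjusted p = 0.135), and XLOC_023019, which overlaps Ssh1, had -0.74 (adjusted p = 0.0592); neither passed.

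These 4 assembled genes were the ones called, 2 higher and 2 lower, and 16 were called when adjusted over the assembled genes alone, 2 higher and 14 lower. The called share was 0.901% of assembled and 0.601% of RefSeq genes, an odds ratio of 1.5 (95% interval 0.397 to 4.04, p = 0.351, Fisher's exact test, two-sided, across genes that are not independent replicates). The count was 0 without control replicate 1 and 0 without control replicate 2 by edgeR, with 55 genes at an unadjusted p under 0.05 in each, 44 without high-fat replicate 1, and 17 without high-fat replicate 2.

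**Figure D4:**
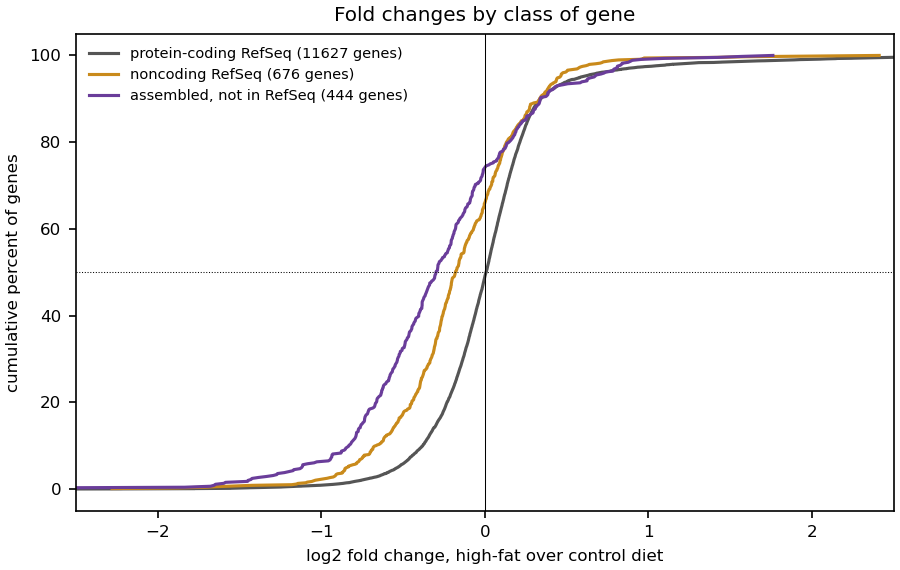
Cumulative percent of genes (vertical axis) at or below a log2 fold change of high-fat over control diet (horizontal axis) for protein-coding RefSeq, noncoding RefSeq and assembled genes. The medians are 0.0071, -0.18 and -0.30, and 74.1% of assembled genes lie below 0.

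The log2 fold changes of assembled genes were weakly correlated with those of their nearest measured and named RefSeq gene. Over 444 pairs Pearson's r was 0.230 (permutation p = 2e-05; adjusted over the 7 sets of pairs or scalings 3.5e-05) and Spearman's rho 0.2999 (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted 1.17e-05). In 55 pairs the genes overlapped, and without these r was 0.268 over 389 pairs. It was 0.2225 over 208 pairs within 10 kb and 0.2414 over 236 pairs farther apart, so it did not fall with distance. The permutation also breaks any trend along a chromosome, so its p does not show a relation particular to nearest neighbours. The median of the neighbours was -0.040, against -0.30 for the assembled genes.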

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

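The fit without overlapping genes, the fit with the GC content and exon length trend removed and the choice of named neighbours were made after seeing the data. The count of 78 called genes was 80, 85 and 93 with other size factors, 70 with RefSeq genes only, 62 without overlapping genes and 61 without robust fitting. It moved to 293 at an adjusted p under 0.10, 43 with a 2-fold minimum, 522 with no filter, 46 with a CPM filter, 356 by DESeq2, 28 by limma-voom, 510 by edgeR's exact test and 9 with the GC content and exon length trend removed, which left out assembled genes and RefSeq genes without a GC value; of the 78, 76 were among the DESeq2 calls, 24 among those of limma-voom and 8 among those with the trend removed. A stricter or looser threshold gives the first 2 of these by construction; for the others the cause was not tested. Leaving out a library gave 3 to 823. The lone library left in a diet is then assumed to vary like the other diet's, and the prior degrees of freedom were 7.15 and 6.73 without control replicates 1 and 2 and without limit without either high-fat library, against 7.32 with all 4; with no filter they were 32.6. All 78 genes were kept without either high-fat library, 10 without control replicate 1 and 1 without control replicate 2.

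The count of 4 assembled genes was 4 with each size factor and without overlapping genes. It moved to 16 at an adjusted p under 0.10 and 16 when adjusted over assembled genes alone, 1 with a 2-fold minimum, 26 with no filter, 2 with a CPM filter, 18 by DESeq2, 2 by limma-voom, 2 without robust fitting and 28 by the exact test, and leaving out a library gave 0 to 44; the cause was not tested apart from the thresholds. For the 16 gene lists, counts of 11 to 18 came from the other scalings, filters and gene sets, 0 from an estimated correlation and 2 from fry, which asks another question, and 9 to 18 from leaving out a library. The calls that ended are given with each list; 6 ended without overlapping genes, 3 with no filter, 3 with the GC content and exon length trend removed, 2 with the replicate block, 1 with upper-quartile factors and 0 in the other scalings, filters and gene sets. The neighbour correlation stayed past 0.05 in all 6 alternatives, with r from 0.165, where entries with no gene name were also taken as neighbours (88 pairs), to 0.326 for assembled genes of at least 1 CPM.

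The labels' replicate numbers were tried as a replicate block. Whether the numbers pair the samples is not known: each diet has 2, and the labels do not say what a shared number means. The deviations of same-numbered libraries correlated at 0.0888 across genes. Replicate 2 minus replicate 1 went with GC content in the same direction in both diets (Spearman's rho -0.50 in control and -0.29 in high-fat). With the block 113 genes were called (49 higher, 64 lower, 59 of them among the 78), 4 assembled genes and 14 lists.

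Lists that had not passed, or lost their call, turned direction in some fits, and the cause was not tested. The alternative activation list turned to lower by camera with library totals (median -0.10), a CPM filter (-0.12), RefSeq genes only (-0.11), without overlapping genes (-0.11), and without control replicate 2 (-0.090) or high-fat replicate 2 (-0.21). Without high-fat replicate 2, inflammatory genes (-0.074), interferon-stimulated genes (0.012), immediate-early genes (-0.074) and B cell markers (-0.11) turned. Large peritoneal macrophage markers turned without control replicate 1 (0.34) or high-fat replicate 1 (-0.065, by camera's mean-based direction), and monocyte markers without high-fat replicate 1 (0.25). Over the 4 libraries left out in turn, medians ran from -0.074 to 0.35 for inflammatory genes, -0.21 to 0.077 for alternative activation, -0.31 to 0.012 for interferon-stimulated genes, -0.074 to 0.31 for immediate-early genes, -0.45 to 0.34 for large peritoneal macrophage markers, -0.30 to 0.25 for monocyte markers and -0.11 to 1.28 for B cell markers. None of the 116 genes picked by the rules fixed beforehand changed direction in any fit that tested it; genes chosen later were not followed across fits. Of the 20 genes picked by fold change, 16 passed with a CPM filter, 17 without robust fitting and 18 with the replicate block. Of the called RefSeq genes 26 lie under 5 CPM, and how far depth limits such calls was not tested.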

Other observations

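The tests on neutrophil markers, the marker separation, the neighbours' median, the reads outside gene models and the removal of the GC content and exon length trend were chosen only after the result was seen. So were the called genes named next.

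Some genes were called that the fixed rule does not name, and no list of them was fixed or tested. Postn, encoding the matrix protein periostin, rose from 0.428 ± 0.132 to 2.95 ± 0.523 CPM (SD, n = 2; log2 fold change 2.77, adjusted p = 0.0161, edgeR quasi-likelihood test). Col6a5 rose by 3.43 on the log2 scale, the proteoglycan Bgn from 0.367 ± 0.00850 to 2.08 ± 0.533 CPM, the collagen receptor Ddr2, whose exons overlap an antisense gene, by 2.31, the microfibril gene Fbn1 by 1.90 and the laminin subunit Lama4 by 2.62. The complement inhibitor Serping1 and the cytokine Il33, at 0.203 and 0.114 CPM with control diet, rose by 3.12 and 3.09. Among the lower genes, the semaphorin gene Sema4d fell by 0.81, and the plexin genes Plxna1 and Plxnd1 fell by 0.88 and 0.78.

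Replicates of the same diet also differed by GC content. Spearman's rho between a gene's GC content and its log2 difference, across 12225 genes, was -0.37 for high-fat minus control, -0.50 for control replicate 2 minus replicate 1, and -0.29 for high-fat replicate 2 minus replicate 1.

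The rise of mesothelial and fibroblast markers may come from RNA of such cells in the high-fat samples, as a hypothesis. Both high-fat libraries exceeded both control libraries in 88.2% of the 17 markers, against 26.1% of all genes, which restates the rise and does not decide between such RNA and a change of expression. Markers low with control diet could be kept through the high-fat libraries alone, which raises the share among the markers. Dcn stood at 14.6 CPM with control and 64.8 CPM with high-fat diet, and Col3a1 at 4.05 and 34.2 CPM, so both were present with control diet too. Pdpn, which the control libraries hold at 433 CPM, had 491. Of the 17 markers, 6 exceed 1 CPM with control diet and 5 are in another list. A smaller share of macrophages stays open. The neutrophil markers, picked after their fall was seen, had a median of -0.76 (camera adjusted p = 0.00214, and 0.537 with an estimated correlation). Other cell lists lay on both sides of 0. Medians were 0.73 for B cell, 0.48 for T cell and NK cell, and 0.11 for mast cell and basophil markers. They were -0.47 for eosinophil, -0.16 for endothelial and -0.018 for dendritic cell markers. The larger library of high-fat replicate 1 is argued against, since without it the median of the mesothelial and fibroblast markers was 1.34. Whether diet changed which cells were collected, or expression within them, stays open and untested, and no sort or gate is named in the labels.

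The lower level of assembled genes was set against 3 technical explanations. Low expression is argued against: their median of -0.30 lay below all 10000 RefSeq lists matched on mean CPM (2.5th percentile -0.087, lowest -0.14). Reads shared with the nearest RefSeq gene are argued against as the whole cause, since those genes had a median of -0.040 (95% interval of 10000 bootstrap draws over pairs -0.079 to -0.012). A lower yield of nuclear or unspliced RNA stays open. The share of uniquely aligned reads in no gene model was at most 24.6% in the high-fat and at least 25.7% in the control libraries, but as a share of all counted lines these reads made up 14.1% to 14.2% and 13.5% to 15.0%, which did not separate the diets. Noncoding RefSeq genes held 2.65% and 2.51% of gene counts in the control and 1.92% and 2.15% in the high-fat libraries, which did separate them. GC content, which could not be had for assembled genes, the selection of these gene models, which is not given in the sources used here, and an effect of diet itself stay open.

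The lower sterol biosynthesis genes were set against 2 technical explanations. GC content or exon length bias as the whole cause is argued against, since the list's median was -0.64 with that trend removed (camera adjusted p = 3.1e-11), although the members called over all genes went from 4 to 0, and all called genes from 70 with RefSeq genes only to 9. Dilution by RNA of other cells as the whole cause is argued against, since the sterol genes lay 0.45 below the general macrophage markers. This difference of medians was -0.45 (p = 0.0003, permutation of the members, two-sided). The p runs across genes, which are not independent replicates, and does not measure the spread between samples. Whether a change in which cells were collected lowered the sterol genes was not tested. A response of macrophages to diet may be considered, as a hypothesis that was not tested. Variation shared by these genes between samples stays open. Their estimated correlation was 0.29, and camera with it gave an adjusted p of 0.537, but with 2 degrees of freedom that test cannot decide the question.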
